A study of Drosophila melanogaster with 5 samples.

How the data were processed

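Total RNA was extracted with Trizol from dissected adult ovaries and made into directional RNA-seq libraries, per the labels' protocols. Reads were processed with FastQC 0.11.8, Trim Galore 0.6.6, STAR 2.7.5b and Salmon 1.2.1 with the dm6 genome build, per the submitters' processing notes, which as used here give no order, settings, annotation or strand setting. The authors deposited 1 table of estimated counts per gene for all 5 libraries, neither scaled nor whole: between 5.33% and 9.29% of values per library had a fractional part. All value columns were matched to samples by the sample descriptions. Groups came from the sample titles. The series design text speaks of duplicates, while the labels give 2 knockout and 3 control libraries, and all 5 were used.

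Gene identifiers were matched to the Ensembl 115 annotation of BDGP6.54, which uses the dm6 coordinates: 14048 of 14094 (99.7%) were found. Of the counts, 11.7% to 17.3% per library fell on 21 genes with rRNA in their symbol, mostly rRNA pseudogenes, and the 10 most abundant genes took 15.2% to 20.3%. Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the groups, which left 9241 genes and at least 99.97% of the counts of each library. Scaling factors were from TMM (0.941 to 1.04). The comparison, knockout minus control, was fitted with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3 with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.321. Standard errors of log2 fold changes are the size of the fold change divided by the square root of the F statistic. Depth limits low genes: 3 counts correspond to 0.0612 CPM in the deepest library and 0.343 CPM in the shallowest. Folds against a group at 0 use a floor of 3 counts over the group, 0.0351 CPM for the knockout and 0.05 CPM for the control. Ratios with 1 to 3 counts carry an exact Poisson interval at 95%, which like the floors covers counting error only.

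Before the data were examined, 31 gene lists were fixed from textbook knowledge: insulator and architectural proteins, nucleoporins, germline-enriched and cytosolic and mitochondrial ribosomal proteins, stem cell and cyst genes, meiotic genes, oocyte and maternal genes, vitelline membrane, chorion and yolk genes, follicle cell regulators, the piRNA pathway, heterochromatin, Polycomb and Hox genes, cell cycle, heat shock, immune, cell death and detoxification genes, markers of testis, muscle, fat body, oviduct and spermatheca, hemocytes and matrix, neurons and gut, oxidative phosphorylation and proteasome subunits, and mitochondrially encoded genes. For each, called members were counted over all tested genes and adjusted over the list alone. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01). Of these, 13 were called, 7 higher and 6 lower, and 0 with an estimated correlation, while fry, which asks whether a list's own genes move on balance one way, called 15. The version of camera with an estimated correlation draws its error from 5 libraries only, so it has little power here. The median log2 fold change of all tested genes was 0.11.

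Named genes followed a rule also fixed before the data were examined. BEAF-32 was always named. So were the 10 higher and 10 lower called genes with the largest fold change, a mean of at least 10 CPM in the higher group and no overlap between groups, with further genes until 5 had a symbol other than a CG or CR number. Each list gave at most 4 called members with the smallest p and 2 uncalled members with the highest CPM. The genes stwl, Nup154, Nup107, Nup98-96, RpS19b, blanks, egg, wde, bam, osk, CTCF, Cp190, aurA and CG3281 were named whatever their result.

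Shares of called genes per chromosome arm and within 1000000 bases of BEAF-32 were tested with Fisher's exact test, and head-to-head pairs with logistic regression and 1000 random pairings within 10 expression bins (scipy 1.17.1, statsmodels 0.14.6). With 2 against 3 libraries, an exact permutation test of a single value cannot give a p under 0.1, since there are 10 groupings, so list shares of counts are given without one.

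No libraries were duplicates: the chi-square per degree of freedom was lowest between controls 2 and 3, at 12.9. The methods were tested on simulated counts for 9241 genes with changes planted between the same 5 libraries. edgeR recovered 10 of 100 genes changed 2-fold and 68 of 100 changed 4-fold, with 13 false calls. DESeq2 1.42.0 recovered 35 and 81 with 65 false calls, and limma-voom 5 and 66 with 9. Only these genes and a planted list were changed, a far smaller share than the 41.5% called in the data. The rates of recovery and of false calls therefore need not hold for the data. camera found the planted list (adjusted p = 6.92e-25) and called 1 of 27 unchanged lists, and 6 of 6 checks of the position tests passed. The simulated genes varied independently, so the camera check does not test the preset correlation of 0.01. In the data the estimated correlation reached 0.867 for chorion genes and 0.9 for mitochondrially encoded genes.

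Alternatives were other scalings, DESeq2, limma-voom, other filters, a replicate block, each library left out, a stricter threshold, and chromosome 3 left out, for which the control's balancer chromosomes were the reason. Chosen after seeing the data were thinning to the total count of the shallowest library, control 1 as the only control, TMM factors over 4 germline lists, depth class as a term and position tests at a mean of at least 10 CPM. The 4 germline lists were stem cell and cyst genes, meiotic genes, oocyte and maternal genes, and the piRNA pathway. Depth class puts libraries with over 50% of the deepest library's counts, which are both knockouts and control 1, apart from controls 2 and 3, so the genotype effect in that fit rests on 1 control library. No GC content was computed because no genome sequence was used here.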

Results

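RNA from whole ovaries of adult Drosophila melanogaster, dissected 1 to 3 days after eclosion, was sequenced in 5 libraries. There were 2 libraries of a BEAF-32-AB knockout and 3 of a control line labelled as wild type with nosGAL4, a driver that expresses the GAL4 activator in the germline. The control also carries balancers of chromosome 3, which the knockout label does not name. Other differences between the stocks are therefore not separated from that of BEAF-32. BEAF-32 is an insulator protein that binds near promoters. The series title places the comparison in a study of genome organization, nuclear pore complex formation and germline differentiation, so it asks which ovarian transcripts differ when BEAF-32 is altered. The knockout libraries held 38820176 and 47805964 estimated counts, control 1 held 41105107, and controls 2 and 3 held 8448850 and 10388643. Of 14094 genes in the table, 9241 had enough counts to be tested. The labels do not say whether the libraries came from separate groups of flies, so the p-values measure the spread between these libraries, part of which may be technical. Values are means of normalized read counts scaled to library size (CPM) ± SD, with n = 2 for the knockout and n = 3 for the control, and fold changes are log2, knockout minus control, with their standard error (SE). Unless camera is named, adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

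BEAF-32 itself (FBgn0015602, chromosome 2R, 14770469 to 14772630, plus strand, dm6) was lower in the knockout but still present. Its level was 52.4 ± 1.34 CPM in the knockout and 120 ± 30.6 CPM in the control, a log2 fold change of -1.19 (SE 0.26, adjusted p = 0.0157 by edgeR). The single libraries gave 53.4 and 51.5 CPM in the knockout and 85.4, 132 and 143 CPM in the control. The labels do not say which part of the gene is altered, so remaining transcript neither checks nor contradicts them. The call was lost without knockout 1 (-1.26, adjusted p = 0.107), without knockout 2 (-1.17, adjusted p = 0.126), and with scaling over germline genes (-0.87, adjusted p = 0.0504).

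By camera with a preset correlation, the eggshell, oocyte and cell cycle lists fell in the knockout, and the muscle, extracellular matrix, follicle cell regulator and ribosomal protein lists rose. None of these list calls held with an estimated correlation (adjusted p = 0.131 to 0.622). That version draws its error from 5 libraries only and has little power: it called 0 of 28 lists. It therefore cannot decide whether a list call is sound. By fry, which asks only whether a list's own genes move one way, all of the lists just named were called (adjusted p = 0.000281 to 0.0244). In all, 3831 of the 9241 tested genes (41.5%) were called at an adjusted p under 0.05, 2102 of them higher and 1729 lower. A log2 fold change of at least 1 in size was found for 2859 of these, 1729 higher and 1130 lower. The libraries of the 2 genotypes did not overlap for 3830 of the called genes and for 69.1% of all tested genes, where chance gives 20%. The first principal component, with 78.7% of the variance, separated the genotypes, and the second, with 11.7%, separated control 1 from the other libraries. The number of called genes was 878 without knockout 1, 1031 without knockout 2 and 6083 without control 1. Of 105 called genes among the 121 followed by name, 30 lost their call without knockout 1 and 25 without knockout 2. Controls 2 and 3 form a shallow depth class with no knockout library. Within the deep class, with control 1 alone as control, 5949 genes were called, but the error of that fit is the spread between the 2 knockout libraries only, so this count carries no check against control variation. With depth class as a term, where control 1 is also the only deep control, 5053 were called, including 3602 (94%) of the 3831 in the same direction and 0 in the opposite one. Calls were 54.9% higher, but 74.4% higher (2997 against 1031) when the scaling factors came from germline genes. These germline genes include the oocyte and maternal list, which itself fell (median -2.0 in the main fit). This scaling can therefore raise all other genes by construction and is not a neutral reference.

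**Figure D1:**
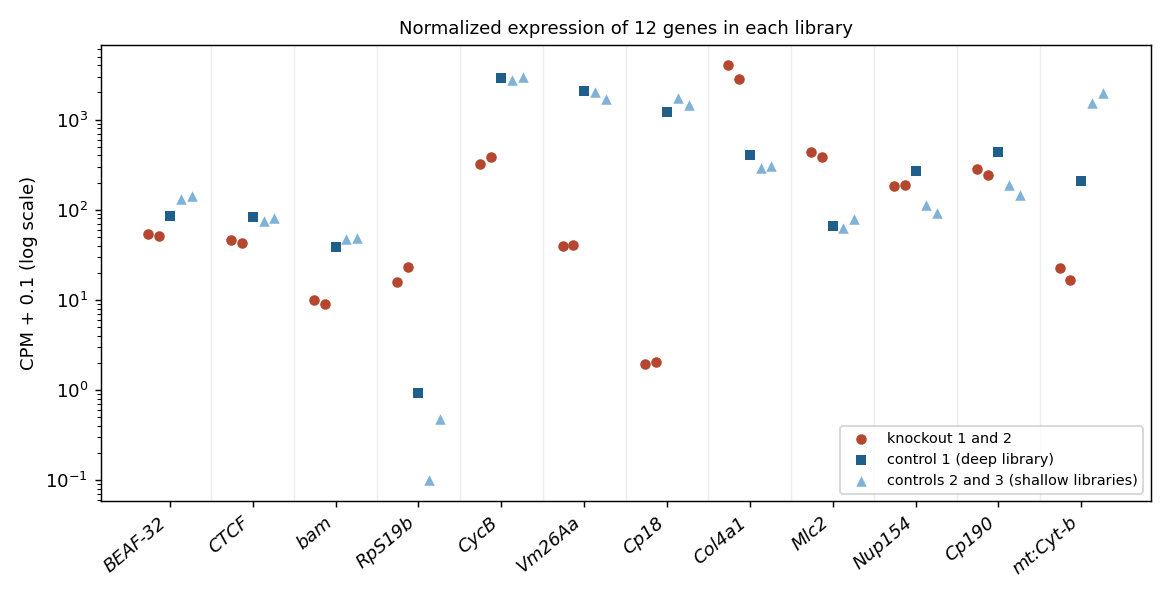
CPM plus 0.1 on a log axis for 12 genes, with 1 point per library: circles are the 2 knockout libraries, the square is control 1 and triangles are controls 2 and 3. Cp18 lay near 1.90 CPM in the knockout and 1466.5 CPM in the control, while Nup154 and Cp190 were higher in control 1 than in every other library.

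The chorion genes, which encode the outer eggshell made late in oogenesis, were nearly absent from the knockout. All 9 fell (9 also adjusted over the list alone), with a median log2 fold change of -11.5 (camera adjusted p = 8.94e-28, and adjusted p = 0.142 with an estimated correlation). Cp18 was at 1.90 ± 0.09 CPM in the knockout and 1466.5 ± 269.7 CPM in the control (-9.59, SE 0.33, adjusted p = 0.00024), and Cp7Fb at 2.04 ± 0.09 and 436 ± 21.2 CPM (-7.74, SE 0.23, adjusted p = 0.00024). Chorion genes took 0.000776% of knockout counts and 1.58% of control counts. Vitelline membrane genes, the inner eggshell layer, fell too: 14 of 17 were lower and 1 higher (15 lower and 1 higher adjusted over the list alone), with a median of -4.91 (camera adjusted p = 2.84e-22, and adjusted p = 0.131 with an estimated correlation). Vm26Aa went from 1918 ± 200 CPM in the control to 39.8 ± 0.49 CPM (-5.59, SE 0.22), dec-1, an eggshell assembly protein, changed by -4.91 (SE 0.26), and yellow-g by -9.55 (SE 0.39). Among the yolk protein genes, Yp3 fell (-1.42, SE 0.27, adjusted p = 0.0105), whereas Yp1 (-0.75, SE 0.33, adjusted p = 0.122) and Yp2 (-0.54, SE 0.31, adjusted p = 0.212) were not called, which makes 1 of 3 lower, likewise 1 adjusted over the list alone. With depth class as a term Yp1 (-1.22, adjusted p = 0.00208) and Yp2 (-1.02, adjusted p = 0.00209) were called lower as well. Yp3 lost its call without knockout 1 (adjusted p = 0.0692) or knockout 2 (adjusted p = 0.1).

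Oocyte polarity and maternal genes were largely lower: 20 of 29 fell and 2 rose, with the same counts adjusted over the list alone and a median of -2.0 (camera adjusted p = 7.74e-10, and adjusted p = 0.142 with an estimated correlation). Cyclin B, CycB, was at 353 ± 43.7 CPM in the knockout and 2882 ± 102 CPM in the control (-3.03, SE 0.19, adjusted p = 0.00051). The anterior determinant bcd (-3.57, SE 0.24), the Cdc25 phosphatase twe (-3.07, SE 0.20) and swa, needed for bcd RNA localization (-2.75, SE 0.18), fell. The posterior determinant osk was at 767 ± 72.8 and 1172 ± 404 CPM and was not called (-0.61, SE 0.31, adjusted p = 0.157), but was lower with depth class as a term (-1.09, adjusted p = 0.00095). Cell cycle and DNA replication genes had 24 of 38 members lower and 0 higher (26 and 0 adjusted over the list alone), with a median of -0.90 (camera adjusted p = 1.14e-07, and adjusted p = 0.142 with an estimated correlation). CycB3 changed by -2.35 (SE 0.17) and Orc1, a subunit of the origin recognition complex, by -2.0 (SE 0.16). The cell cycle list had 10 members lower without knockout 1 and 10 without knockout 2.

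**Figure D2:**
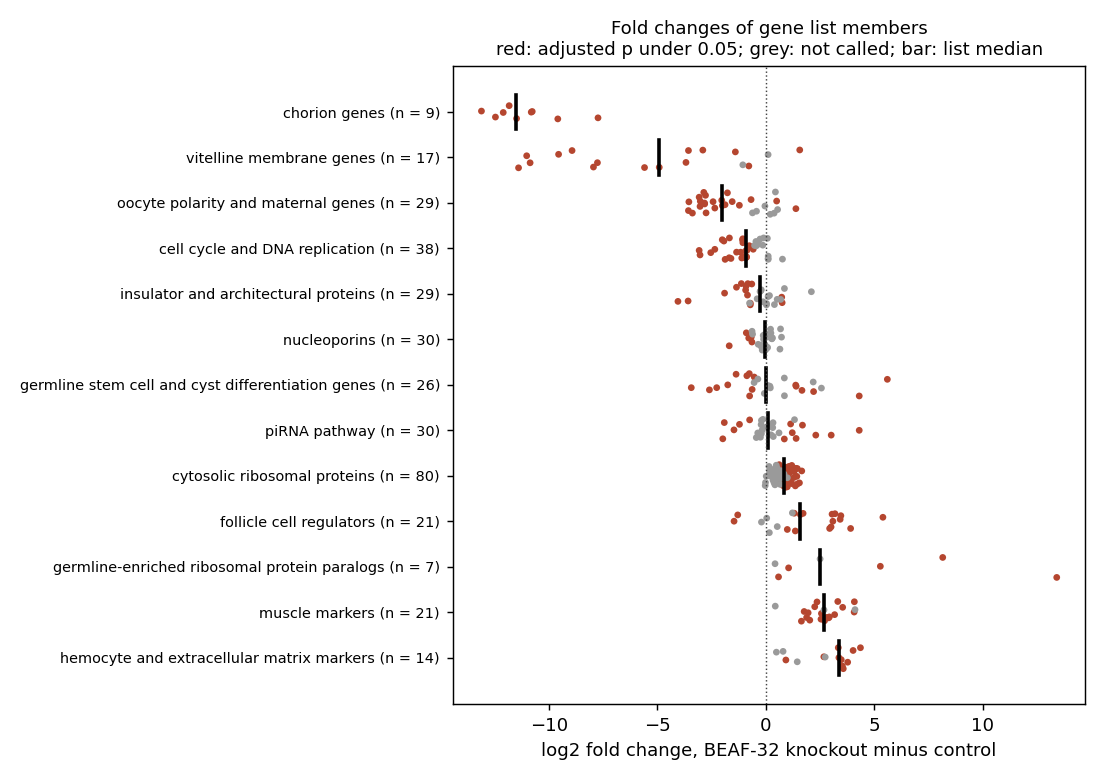
Log2 fold change, knockout minus control, of each tested member of 13 gene lists, with 1 point per gene, red where called at an adjusted p under 0.05 and grey otherwise, and a bar at the list median. Medians run from -11.5 for chorion genes to 3.36 for hemocyte and extracellular matrix markers, and the nucleoporin median is -0.06, or 0.28 when scaled over germline genes.

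Genes of early germline differentiation moved both ways. Of 26 stem cell and cyst genes 6 rose and 10 fell, with the same counts adjusted over the list alone, and the list was not called (camera, Down, adjusted p = 0.465, median 0.02, mean 0.30, so that the test and the median differ in sign). The differentiation factor bam fell from 44.9 ± 5.24 to 9.34 ± 0.57 CPM (-2.26, SE 0.19, adjusted p = 0.00089), and brat fell (-1.75, SE 0.18). The translational regulator nos changed by -3.43 (SE 0.23), and since the control carries a nos-driven transgene whose sequence may share reads with nos, its value is uncertain. The somatic piRNA factor fs(1)Yb rose (4.31, SE 0.48), and blanks, at 2.79 ± 0.07 and 0.66 ± 0.50 CPM, was not called (2.19, SE 0.97, adjusted p = 0.119). It was called higher without control 1 (1.55, adjusted p = 0.0306), with limma-voom (3.07, adjusted p = 0.0282) and with depth class as a term (4.77, adjusted p = 0.00228). Meiotic genes were split as well, with 6 of 24 higher and 7 lower (the same adjusted over the list alone, camera adjusted p = 0.568, median -0.47, mean 0.43). The segregation factors mtrm (-4.32, SE 0.28) and nod (-2.61, SE 0.18) fell, and the cohesion factor sunn (4.92, SE 0.49) and the crossover factor vilya (4.37, SE 0.55) rose. Of 30 piRNA pathway genes 8 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.896, median 0.11), among them armi (3.02, SE 0.49, but adjusted p = 0.0578 without knockout 1) and squ (-1.98, SE 0.17). The balance of these lists depended on the settings: with scaling over germline genes 7 stem cell and cyst genes were higher and 5 lower, and 6 meiotic genes higher and 5 lower, while with depth class as a term 8 piRNA genes were higher and 9 lower. Without knockout 1, stem cell and cyst genes had 2 higher and 3 lower, meiotic genes 3 and 2, and piRNA genes 1 and 1, and without knockout 2 they had 2 and 5, 3 and 2, and 2 and 1.

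Ribosomal protein paralogs listed beforehand as germline-enriched, without a check of single members, rose in 5 of 7 cases, with 0 lower and the same counts adjusted over the list alone (median 2.51, camera adjusted p = 0.00015, and adjusted p = 0.289 with an estimated correlation). The size of that median is loose: with 1 library left out it ran from 2.23 (without control 2) to 5.04 (without control 3). RpS19b went from 0.40 ± 0.42 CPM in the control to 19.5 ± 5.17 CPM (5.29, SE 0.81, adjusted p = 0.00524), RpS10a from 0.15 ± 0.18 to 36.0 ± 4.77 CPM, and RpS14b changed by 1.05 (SE 0.19). Without knockout 1 or knockout 2, RpS19b (adjusted p = 0.0535 and 0.0647) and RpS14b (adjusted p = 0.0572 and 0.092) were not called. RpL22-like had 0 counts in all 3 controls and 47.1 ± 11.6 CPM in the knockout, at least 943-fold higher against a floor of 3 counts over the group. Reads shared between paralogs can be split by the counting, so these levels are uncertain. The canonical cytosolic ribosomal proteins rose as well, 52 of 80 with 0 lower (59 and 0 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 9.08e-05, and adjusted p = 0.622 with an estimated correlation). Of these 80, 14 were higher without knockout 1, 8 without knockout 2 and 27 without control 2, and of the 7 paralogs 2 were higher without either knockout library in turn. RpS5a changed by 1.66 (SE 0.17), RpL28 by 1.40 (SE 0.17) and RpS7 by 1.15 (SE 0.15). Together they took 12.8% of knockout counts and 7.52% of control counts.

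Insulator and architectural protein genes had 12 of 29 members lower and 2 higher, with the same counts adjusted over the list alone (camera, Down, adjusted p = 0.0221, and adjusted p = 0.575 with an estimated correlation). Their median was -0.26, or 0.08 when scaled over germline genes, where 6 were lower and 5 higher. Without knockout 1 or knockout 2, 2 were lower and 0 higher, and without control 1 there were 12 lower and 8 higher. The boundary factors insv (-4.05, SE 0.21) and Elba2 (-3.58, SE 0.32), the kinase aurA (-1.90, SE 0.29, adjusted p = 0.00522) and CTCF (44.2 ± 2.38 against 79.3 ± 3.63 CPM, -0.84, SE 0.15, adjusted p = 0.0082) fell. With scaling over germline genes CTCF changed by -0.50 (adjusted p = 0.048). The others named beforehand were not called: stwl at 0.86 (SE 0.47, adjusted p = 0.190), CG3281 at -0.26 (SE 0.19, adjusted p = 0.301) and the insulator cofactor Cp190 at 0.04 (SE 0.48, adjusted p = 0.959). The list call was lost without knockout 2 (adjusted p = 0.0506), without control 1 (adjusted p = 0.206) and after thinning all libraries to the same total count (adjusted p = 0.0569), and the calls of CTCF (adjusted p = 0.0906 and 0.11) and aurA (adjusted p = 0.0569 and 0.0597) without knockout 1 or knockout 2. Cp190 was called in opposite directions, lower with depth class as a term (-0.73, adjusted p = 0.00897) and higher without control 1 (0.66, adjusted p = 0.00406), where stwl was also called higher (1.49, adjusted p = 9.14e-05).

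Nucleoporin genes, which encode the nuclear pore, were not called as a list: 5 of 30 were lower and 0 higher (1 lower adjusted over the list alone), with camera adjusted p = 0.322 and a median of -0.06, or 0.28 when scaled over germline genes, where 1 was lower and 4 were higher. Without knockout 1 or knockout 2, 1 was lower. The mRNA export factor Gle1 fell (-1.68, SE 0.20, adjusted p = 0.00237), as did Nup54 (-0.78, SE 0.17, adjusted p = 0.0157), Nup58 (-0.64, SE 0.16, adjusted p = 0.0231) and Nup37 (-0.90, SE 0.25, adjusted p = 0.0340). Nup154 was at 185 ± 3.13 and 159 ± 97.9 CPM (0.22, SE 0.47, adjusted p = 0.726), Nup107 changed by 0.24 (SE 0.15, adjusted p = 0.240) and Nup98-96 by 0.28 (SE 0.31, adjusted p = 0.492), and these were not called. Nup54 (-0.45, adjusted p = 0.108), Nup58 (-0.30, adjusted p = 0.232) and Nup37 (-0.55, adjusted p = 0.128) were not called with scaling over germline genes, nor without knockout 1 (adjusted p = 0.134, 0.155 and 0.188) or knockout 2 (adjusted p = 0.119, 0.166 and 0.196), and Nup37 also not without control 3 (adjusted p = 0.0825), while Nup107 was called higher with that scaling (0.58, adjusted p = 0.0348). Control 1 decided the direction of other calls. With depth class as a term the list was called lower (10 of 30 lower, 0 higher, adjusted p = 0.0483) and so was Nup154 (-0.55, adjusted p = 0.0143), but without control 1 the list was not called (8 higher, 9 lower, adjusted p = 0.872), and Nup154 (0.85, adjusted p = 0.00032) and Nup98-96 (0.63, adjusted p = 0.00113) were called higher.

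Silencing genes were not called as lists. Of 15 heterochromatin genes 2 rose and 5 fell (camera adjusted p = 0.250, median -0.59, mean 0.04), and of 21 Polycomb group genes 2 rose and 7 fell (camera adjusted p = 0.102, median -0.26, or 0.07 when scaled over germline genes), with the same counts adjusted over each list alone. Pc (-2.08, SE 0.15), the histone demethylases Kdm4A (-1.42, SE 0.20) and Kdm4B (-1.31, SE 0.20), and Su(var)3-7 (-1.49, SE 0.25) fell. The methyltransferase egg (-0.14, SE 0.14, adjusted p = 0.453) and its cofactor wde (0.39, SE 0.58, adjusted p = 0.607) were not called. Control 1 decided the value of wde, which was called higher without it (1.201, adjusted p = 0.000788) and was at -0.49 with depth class as a term (adjusted p = 0.0917). With control 1 alone it was called lower (-0.61, adjusted p = 0.00242), with an error from the 2 knockout libraries only. Of 3 tested Hox genes, abd-A (3.93, SE 0.72) and Antp (2.78, SE 0.54) rose, 2 also adjusted over the list alone. Without knockout 1 or knockout 2, Kdm4A (adjusted p = 0.064 and 0.0541), Kdm4B (adjusted p = 0.0644 and 0.0686), Su(var)3-7 (adjusted p = 0.0732 and 0.0795), abd-A (adjusted p = 0.073 and 0.060) and Antp (adjusted p = 0.151 and 0.118) were not called, nor was any heterochromatin gene or more than 1 Polycomb gene. Without control 1, 6 Polycomb genes were higher and 9 lower. With depth class as a term, the heterochromatin (adjusted p = 0.0399) and Polycomb (adjusted p = 0.00348) lists were called lower.

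Follicle cell regulators, muscle markers and matrix markers rose as lists. Of 21 follicle cell regulators 14 rose and 2 fell, with the same counts adjusted over the list alone (median 1.60, camera adjusted p = 0.00072, and adjusted p = 0.622 with an estimated correlation). The follicle cell fate gene eya went from 16.6 ± 3.18 to 179 ± 21.9 CPM (3.43, SE 0.22, adjusted p = 0.00052), and the adhesion protein Fas3 changed by 3.01 (SE 0.24). Fewer regulators were higher without knockout 1 (5), knockout 2 (6), control 2 (9) or control 3 (8). Muscle markers had 18 of 21 members higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 2.69 (camera adjusted p = 4.36e-11, and adjusted p = 0.142 with an estimated correlation). The myosin light chain Mlc2 was at 414 ± 34.6 and 69.7 ± 8.76 CPM (2.57, SE 0.18), and tropomyosin Tm2 changed by 2.71 (SE 0.20). Hemocyte and extracellular matrix markers had 10 of 14 higher and 0 lower, the same adjusted over the list alone (median 3.36, camera adjusted p = 1.16e-06, and adjusted p = 0.338 with an estimated correlation). The members with the smallest p were matrix genes: the collagen IV chains Col4a1 (3394 ± 845 against 334 ± 63.5 CPM, 3.35, SE 0.25) and vkg (3.53, SE 0.27), SPARC (3.37, SE 0.19) and the peroxidasin Pxn (4.37, SE 0.37). Muscle markers took 0.669% of knockout and 0.127% of control counts.

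Fat body markers had 7 of 15 higher and 0 lower (10 and 0 adjusted over the list alone, median 2.07, camera adjusted p = 0.00495, and adjusted p = 0.356 with an estimated correlation), with Lip4 at 4.41 (SE 0.17) and the lipoprotein apolpp at 1.70 (SE 0.25, but adjusted p = 0.0619 without knockout 1). Of 10 neuronal markers 4 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0627), among them elav (1.95, SE 0.25, but adjusted p = 0.0577 without knockout 1). The neuronal list was called higher without knockout 1 (adjusted p = 0.0352), knockout 2 (adjusted p = 0.0485) or control 2 (adjusted p = 0.00772). Testis markers had 3 of 12 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.568). Without knockout 1, 3 fat body and 1 neuronal marker were higher, without knockout 2, 5 and 2, and no testis marker was called in either case, while without control 1, 8 neuronal and 6 testis markers were higher. Of 4 oviduct and spermatheca markers Send1 rose, with 0 counts in the controls and at least 193-fold higher, and Hr39 (-1.25, SE 0.16) and Oamb (-0.87, SE 0.24) fell, with the same counts adjusted over the list alone. Oamb was not called without knockout 1 (adjusted p = 0.153), knockout 2 (adjusted p = 0.220) or control 3 (adjusted p = 0.0548), nor with scaling over germline genes (-0.53, adjusted p = 0.153). Without knockout 1 Hr39 (adjusted p = 0.051) and Send1 (adjusted p = 0.0818) lost their call. Of 9 gut markers 0 were called by edgeR, and 0 adjusted over the list alone (camera adjusted p = 0.672). Their median of -4.88 (-4.07 with genes at 0 set to their bound) came with 0.0158% of counts in control 1 against 0.00026% in control 2, and Jon65Aiv, a digestive protease, had 40.7 CPM in control 1 and 0 counts in the other controls. With depth class as a term, where control 1 sets the comparison, the gut list was called lower (7 of 9 lower, adjusted p = 0.00334).

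**Figure D3:**
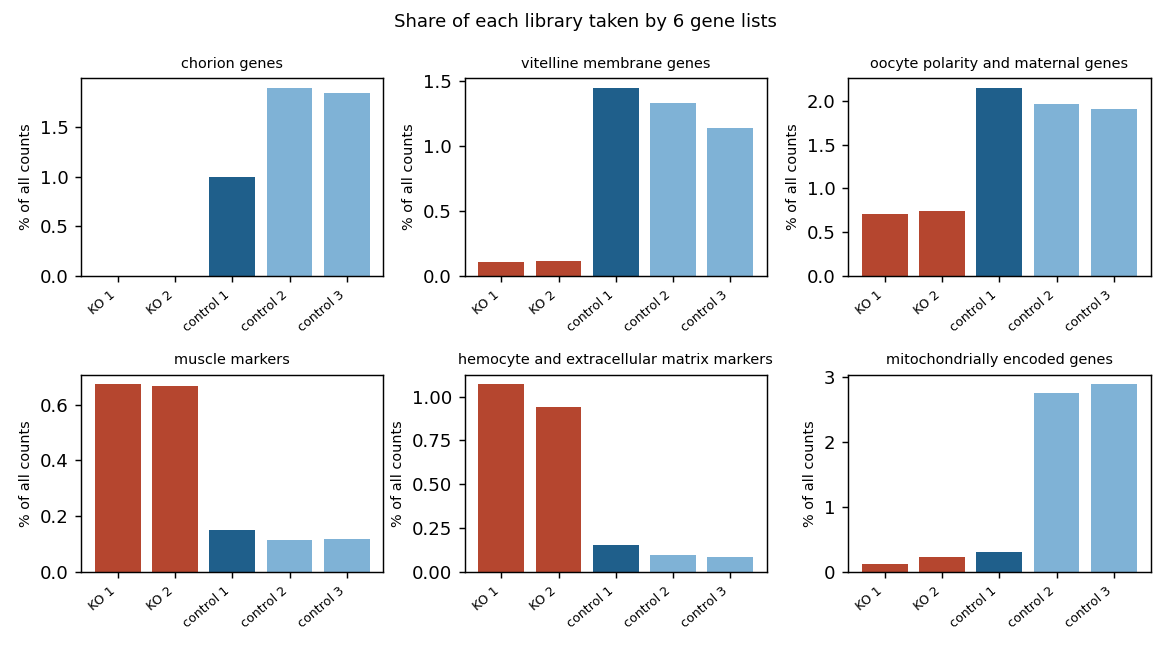
Percent of all counts taken by 6 gene lists in each library, with 1 bar per library: red bars are the knockout, the dark blue bar is control 1 and light blue bars are controls 2 and 3. Chorion genes took 0.995%, 1.90% and 1.85% in the controls, and mitochondrially encoded genes took 0.313% in control 1 against 2.76% and 2.89% in controls 2 and 3.

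Mitochondrially encoded transcripts were lower in the knockout but also varied among the controls. Of 10 tested, 5 were lower and 0 higher (6 and 0 adjusted over the list alone, median -4.44, camera adjusted p = 0.0108, and adjusted p = 0.622 with an estimated correlation). The list was not called by fry either (adjusted p = 0.182). The cytochrome b gene mt:Cyt-b was at 22.3 and 16.4 CPM in the knockout and at 207, 1515 and 1982 CPM in the controls (-5.99, SE 1.12, adjusted p = 0.0102). Its call was lost without knockout 1 (adjusted p = 0.0851) or knockout 2 (adjusted p = 0.094), and with depth class as a term its change was -3.42 (adjusted p = 6.34e-06). The list took 0.118% and 0.237% of knockout counts, and the list's call was lost with depth class as a term (median -1.38, adjusted p = 0.0601). Among nuclear genes for mitochondrial proteins, 12 of 62 oxidative phosphorylation subunits rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.258, median 0.31). Of 73 mitochondrial ribosomal proteins 5 rose and 3 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.505, median -0.01, or 0.32 when scaled over germline genes). Of 32 proteasome subunits 0 were called by edgeR, and 0 adjusted over the list alone (camera adjusted p = 0.258, median -0.22, or 0.12 when scaled over germline genes). With depth class as a term, the oxidative phosphorylation (median 0.59, adjusted p = 2.99e-06) and mitochondrial ribosomal (median 0.34, adjusted p = 0.0168) lists were called higher. Without knockout 1 or knockout 2 no member of these 4 lists was called. Without control 1, 25 oxidative phosphorylation genes were higher and 4 lower (2 higher without control 2 or control 3), 7 mitochondrial ribosomal genes higher and 32 lower, and 1 proteasome gene higher and 15 lower.

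The largest single changes included genes with 0 counts in 1 genotype. Beside RpL22-like, CG43739 (at least 834-fold), SkpE (at least 293-fold) and CG43843 (at least 242-fold) had 0 counts in all controls and were higher in the knockout. The glutathione transferase GstE10 had 1 count over the controls, a ratio of 3020 (95% counting interval 542 to 119000), CG15599 had 3 counts, a ratio of 4590 (1570 to 22200), and the cytochrome P450 Cyp4p2 had 3 counts, a ratio of 2620 (897 to 12700). CG12477 had 1 count, a ratio of 1050 (188 to 41500), and ATPsynepsilonL 2 counts, a ratio of 631 (175 to 5210), while CG9411 had 7 counts, all in control 1, and 110 ± 32.5 CPM in the knockout (9.92, SE 0.58). In the other direction CG15571 (at least 2380-fold lower), CR43482 (at least 1400-fold) and CG13737 (at least 387-fold) had 0 counts in the knockout. His1:CG33858 was also at 0 there (at least 387-fold), but it is 1 copy of a repeated histone gene and shares reads with the others. The rest of the 10 most reduced genes held Cp15, Cp16, Cp19 and Cp36, together with CG13083 and CG32642. In all, 96 called genes had 0 counts in the controls and 16 had 0 counts in the knockout, and such folds and intervals cover counting error only.

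Genes of head-to-head pairs, whose starts lie within 1000 bases and point away from each other, an arrangement at which BEAF-32 is known to bind, were called less often. Of 3900 such genes 36.5% were called, against 45.1% of other genes, an odds ratio of 0.696 (95% interval 0.638 to 0.760). This came from a logistic regression over the tested genes (n = 9241) with mean CPM as a covariate (p = 4.69e-16). It was adjusted for expression level only, not for tissue or stage specificity. BEAF-32 binding was not measured here, so the lower share is not a result about its binding sites. The log2 fold changes of 1867 pairs correlated across genes (Pearson r = 0.222, Spearman rho = 0.139), while random partners of like expression averaged 0.0146 (permutation p = 0.001, the smallest that 1000 pairings can give). By chromosome arm, 44.4% of genes on 2L were called, 3.64 points above the other arms (adjusted p = 0.0209 by two-sided Fisher's exact test over 6 arms), and 38.9% on 3R, 3.32 points below them (adjusted p = 0.0209). Within 1000000 bases of BEAF-32, 67 of 169 genes were called (39.6%, against 42.1% on the rest of the arm, p = 0.568 by two-sided Fisher's exact test). Genes are not independent replicates, and neither arm passed with depth class as a term (adjusted p = 0.402 for both) or among genes with a mean of at least 10 CPM (adjusted p = 0.182 for 2L and 0.202 for 3R). At a log2 fold change of at least 1 in size, 2L did not pass either (adjusted p = 0.0892).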

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

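Thinning, control 1 alone, germline scaling, depth class and position tests at a mean of at least 10 CPM were chosen after the data were seen. Of 3831 called genes, 0 were called in the opposite direction under any alternative. Counts of calls ran from 3430 to 4615 over scalings, tools and filters other than a mean of at least 10 CPM, and thinning gave 3526. A mean of at least 10 CPM gave 1332 higher and 1773 with a log2 fold change of at least 1, among 6614 tested genes. Chromosome 3 left out gave 2303 (1283 higher, 1020 lower, 1732 with a log2 fold change of at least 1). An adjusted p under 0.01 gave 1722 (912 higher, 810 lower, 1618 with a log2 fold change of at least 1), and BEAF-32, at -1.19, was then not called. Leaving out 1 library at a time gave 878 (without knockout 1) to 6083 (without control 1) calls, 475 to 3352 higher, 403 to 2731 lower and 878 to 3661 with a log2 fold change of at least 1. With 1 knockout library the fit assumes that it varies like the controls. BEAF-32 was then -1.26 and -1.17, and over all left-out libraries it ranged from -1.40 (without control 1) to -1.10 (without control 3). Control 1 alone gave 5949 (3014 lower), with an error from the 2 knockout libraries only, which assumes that the lone control varies like them. Germline scaling shifted the median of all genes by 0.341, gave 1031 lower genes and put BEAF-32 at -0.87 (adjusted p = 0.0504). No count filter shifted that median by 0.16, a mean of at least 10 CPM by -0.134 and thinning by -0.11. With an estimated correlation, 0 in place of 13 lists were called, but that version has little power with 5 libraries.

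With the replicate number as a replicate block 3261 genes were called. With group means removed, same-numbered libraries correlated across genes at 0.0577 and 0.0475, with 2 pairs only. The deviations of the 2 knockouts mirror each other by construction, so these values show no clear pairing but cannot exclude it. Among named genes the block changed Cp190 to -0.13 and ended the calls of Nup58 (adjusted p = 0.0886), Nup37 (adjusted p = 0.0585), Oamb (adjusted p = 0.117), mt:ND4 (adjusted p = 0.212) and mt:Cyt-b (-4.87, adjusted p = 0.303), while Yp1 (-0.91, adjusted p = 0.0136) and mt:CoI (-1.47, adjusted p = 0.0175) gained one. The oxidative phosphorylation list was called higher (adjusted p = 0.0479).

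Directions turned for genes that were not called with all libraries, and calls went both ways for Cp190, Nup154 and wde: without control 1, Cp190 (adjusted p = 0.00406) and Nup154 (adjusted p = 0.00032) were called higher, as was wde (adjusted p = 0.000788), and with depth class Cp190 (adjusted p = 0.00897) and Nup154 (adjusted p = 0.0143) were called lower, with control 1 as the only deep control. With control 1 alone wde was called lower (adjusted p = 0.00242), as were Cp190 (adjusted p = 0.00189) and Nup154 (adjusted p = 0.00307), but that fit has no spread between controls. What sets control 1 apart was not settled. Cp190 was -0.00186 with library totals, -0.025 without the 50 most abundant genes, -0.0445 with no filter, -0.33 (without control 3) to 0.66 (without control 1) with 1 library left out, -0.85 with control 1 alone and -0.73 with depth class. Nup154 was -0.13 (without control 3) to 0.85 (without control 1) with 1 library left out, -0.66 with control 1 alone and -0.55 with depth class. The gene wde was -0.035 (without control 3) to 1.201 (without control 1), -0.61 with control 1 alone and -0.49 with depth class. Nup98-96 was -0.35 and -0.23 in those last 2 fits, and stwl -0.00594 with control 1 alone. Germline scaling gave CG3281 0.080 and egg 0.20. The mitochondrial ribosomal list had a median of 0.34 with depth class. For chromosome arms, 2L stood 2.76 points above the others at a log2 fold change of at least 1 (adjusted p = 0.0892), 2.05 with depth class (adjusted p = 0.402) and 3.38 at a mean of at least 10 CPM (adjusted p = 0.182). Arm 3R stood at -2.15 (adjusted p = 0.402) and -2.37 (adjusted p = 0.202) in the last 2, and arm 4 at 5.33 with depth class. The difference near BEAF-32 was 0.527 points with a window of 500000 bases.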

Other observations

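The tests of the muscle pattern, of the stage mix, gene length and library preparation behind control 1, of convergent neighbours, and the choice of w, y, CG12782 and Pepck1, were made after the results were seen.

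Stress, immune and detoxification genes moved in both directions. Of 22 immune genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 2.29, camera adjusted p = 0.0122, and adjusted p = 0.254 with an estimated correlation), among them the peptidoglycan recognition protein PGRP-LB (3.11, SE 0.37), the NF-kB factor Dif (3.92, SE 0.55) and Tep2 (4.54, SE 0.72, but adjusted p = 0.0534 without knockout 1). Heat shock genes had 2 of 16 higher and 3 lower, the same adjusted over the list alone (camera, Down, adjusted p = 0.584, median 0.09, or -0.54 with depth class as a term). Hsp26 fell (-3.11, SE 0.24) and Hsp27 fell (-2.05, SE 0.26). Of 21 cell death and damage genes 5 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.693, median 0.03): hid, an activator of apoptosis, rose (2.06, SE 0.20), and the checkpoint kinases grp (-1.96, SE 0.17) and lok (-1.61, SE 0.17) and the caspase Dronc (-1.86, SE 0.16) fell. Detoxification enzymes had 9 of 24 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.513), with Cyp9c1 at 3.65 (SE 0.24) and Cyp6a22 at -2.93 (SE 0.22). Without knockout 1 or knockout 2, the immune list had 2 or 3 higher, the cell death list 1 or 3 higher, and the detoxification list 2 higher in both cases.

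The eye pigment transporter w was at 0.09 ± 0.10 CPM in the knockout and 147 ± 9.89 CPM in the control (-10.71, SE 0.59, adjusted p = 0.00043 by edgeR), and the pigment gene y had 0 counts in the controls and 1.56 ± 0.07 CPM in the knockout. Both are common markers of transgenes and of stock background. CG12782 had 0 counts in the controls and 6.47 ± 0.05 CPM in the knockout, and Pepck1, an enzyme of gluconeogenesis, was at 962 ± 268 and 2.78 ± 1.37 CPM (8.37, SE 0.52).

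Muscle markers were higher in the knockout. If a lower share of eggshell-forming egg chambers were the source, markers of every other tissue would rise alike. Among genes with a mean of at least 10 CPM, the median of 19 muscle genes lay -0.63 on the log2 scale from that of 23 markers of hemocytes and matrix, fat body, neurons, oviduct and spermatheca (2.71 against 3.35, 95% bootstrap interval of the difference -1.15 to 1.24). The interval is too wide to decide, and no gut marker reached that level. Of the 23 markers, 10 were of hemocytes and matrix and 9 of fat body, so other tissues were hardly covered. A lower share of egg chambers, a larger share of muscle-containing tissue such as the ovarian sheath, and a change of expression within somatic cells therefore cannot be told apart here.

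In all, 3831 genes were called between the genotypes. The lower depth of controls 2 and 3 is argued against by thinning, which at the total count of the shallowest library left 3526 calls against 3831. Balancer or flanking sequence is argued against as the main source: the share of called genes on chromosome 3 differed from the other chromosomes by -3.15 points (two-sided Fisher p = 0.00241), and that within 1000000 bases of BEAF-32 from the rest of its arm by -2.43 points (p = 0.568). Other background differences, such as those that w and y may mark, and the altered gene itself stay open. So does a different mix of tissues and egg chamber stages, as chorion genes took 0.000776% of knockout and 1.58% of control counts. A difference in library preparation between control 1 and controls 2 and 3, described below, stays open too.

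Across 6589 genes the difference of control 1 from the other controls correlated with the knockout effect (r = 0.365, bootstrap SE 0.0208, covariance 0.508). In 20 simulations with no effect but the same shared controls, r was -0.023 to 0.0345 and the covariance -0.00578 to 0.00871. A deviation common to the other controls enters both differences with the same sign and raises r by itself. The low simulated r shows that the simulations held no such deviation. They therefore cannot show that 0.365 exceeds what such a deviation alone would give. Depth and gene length are argued against as the whole cause, since r was 0.351 after thinning and 0.288 (bootstrap SE 0.0244) after a length trend was removed, although the difference itself rose with exon length (r = 0.543). The knockout effect against all controls rose with exon length too (r = 0.229), while the knockout minus control 1 hardly did (r = 0.0363). The fold changes given above therefore carry a length trend that came mainly with controls 2 and 3. A different mix of egg chamber stages may contribute, as chorion genes were lower (median -0.71) and muscle genes higher (0.40) in control 1, but vitelline membrane genes were not lower (0.16). A difference in library preparation may contribute too, as mitochondrially encoded genes lay at a median of -3.26, lower in 10 of 10. The labels name no batch, and genes are not independent replicates.

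It was asked whether the shared changes of head-to-head partners (r = 0.222) exceed those of other close neighbours. Across 2673 tandem or convergent neighbours within 1000 bases r was 0.193, and the difference of 0.0296 (bootstrap SE 0.0573) was within its error. By the criterion set before the results were seen, head-to-head partners therefore did not exceed other close neighbours. In a split by orientation, made after the results were seen, 1814 tandem pairs gave 0.237 and 859 convergent pairs 0.0701. The convergent value lay below head-to-head pairs by 0.152 (bootstrap SE 0.0675) and below tandem pairs by 0.167 (SE 0.059). Convergent pairs thus changed together less, while tandem and head-to-head pairs were alike. Whether orientation itself is the reason was not tested.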
